A study of Canis lupus familiaris with 59 samples.

How the data were processed

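RNA from 49 cortisol-secreting adrenocortical tumours of dogs and from 10 normal adrenal cortices was sequenced with CEL-Seq2, a method that tags the 3′ end of each transcript with a library barcode and a unique molecular identifier (UMI), per the labels' protocols. The protocol text speaks of trypsinized cells stored in lysis buffer and of total RNA from a column kit, although the labels describe tumours and cortices. The aligner BWA and the dog genome build CanFam3.1 are named in the submitters' processing notes. The counting program, the annotation release, read filters and any pooling are not given in the sources used here.

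The authors deposited one table of estimated counts, with 28570 Ensembl gene identifiers and 59 libraries. All columns matched the short name of one sample each, and 0 columns were left over. The values are whole numbers, so no rounding was needed, but they are not the plain counts for which the tests were planned. All of them (100%) belonged to the set obtained by rounding the product of 4096 and −ln(1 − k/4096) for whole k, which is the form of a correction for collisions among 4096 possible UMIs. This was read from the values and is recorded in no header or label. In its upper part, from 5 digits on, the set holds only 356 whole numbers, and all 1272 values of that size fell on them. The correction changes nothing below 64 distinct UMIs, turns 2048 UMIs into 2839 molecules, and ends at 34070 for 4095 UMIs. That ceiling was reached 113 times, by 21 genes and in 45 libraries, up to 18 genes in tumour 9. A gene at the ceiling has only a lower limit. Inverting the formula gave the distinct UMIs, which were used as an alternative.

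Gene symbols could not be attached. The table holds identifiers alone, and the reference table at hand paired 0 of the 28570 identifiers with a symbol. The analyses planned around names were therefore not run. These were the fold change of CYP26B1, the 23 gene lists for pathways and cell types, the spread of list scores and the 15 relations between scores. The rule for naming genes, set at the same stage as the tests, covered list members, CYP26B1 and the most variable genes, which all need symbols. Its remaining part took the 6 largest fold changes in each direction among called genes with a symbol and an average log2 CPM at or above the median of the genes tested. That part was applied without the symbol condition and limited to 2 genes in each direction.

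Total counts ranged from 1007920 to 5449077 per library. They were 2170160 ± 827979 (SD, n = 49) in tumours and 1935610 ± 612124 (SD, n = 10) in normals. The lowest total compared with a median of 2112802, and 0 libraries were low enough to be left out by the limit fixed before the data were examined. Genes with too few counts were removed with edgeR's filterByExpr by group, which left 13004 genes and at least 97.4% of each library's counts. Libraries were scaled by TMM, with factors from 0.69 to 1.23. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit, two-sided) over all 59 libraries, with tumour against normal as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the fold change and its F value. Alternatives used DESeq2 1.42.0, limma-voom with sample weights (limma 3.58.1), other scaling and filters, thinning to 1223085 counts in the 54 libraries deep enough, a depth covariate, a block on the number in the titles, and libraries left out. The labels give no batch, animal, sex, age or tumour subtype. Nothing states that each library came from a different dog, so p-values measure the spread between these libraries. No 2 libraries were alike within sampling noise. The closest pair, tumours 44 and 45, differed with a chi-square of 4.56 per degree of freedom, against 20.3 for the median pair. This check cannot show whether 2 libraries came from 1 dog or 1 tumour, since such libraries could also differ by more than sampling noise.

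Similarity between libraries was Pearson's r of log2 CPM (prior count 2) over the 13004 genes. The share of squared distance (1 − r) along the group label and the mean r among normals were tested by permutation against 100000 random sets of 10 libraries, and gene-wise SDs against 999 sets. These measures, and the comparisons of runs of consecutive tumour numbers, were added after the data were seen. The SD comparison took the place of a gene-wise test on absolute deviations, which found none of the changes put into simulated data and was dropped. All 40 runs of 10 consecutive numbers were compared, and tumours 37 to 46 were singled out among them after their values were seen. Beyond this, tumours were grouped by their expression only in a test for 2 classes, and those groups were not compared. On simulated counts with the real means, depths and dispersions and 200 changed genes, the main test recovered 38%, 56%, 88% and 84% of the genes changed by 1.5, 2, 3 and 4-fold, and called 4 unchanged genes. These counts were drawn independently for each gene and library, so genes did not move together as they can in real libraries. The 4 calls therefore do not give the rate of false calls here, where random splits of the real libraries called up to 177 genes.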

Results

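Expression was compared between 49 cortisol-secreting adrenocortical tumours of dogs and 10 normal adrenal cortices. The adrenal cortex is the outer part of the adrenal gland and makes steroid hormones. Tumours that release cortisol are one cause of cortisol excess (Cushing's syndrome) in dogs. The title of the series names 2 tumour subtypes and the gene CYP26B1, which encodes an enzyme that breaks down retinoic acid. The labels assign no tumour to a subtype and the identifiers could not be matched to symbols, so neither was analysed here. Library titles number the tumours 1 to 49 and the normals 1 to 10, and these numbers are used as names below.

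Between 16766 and 22158 genes had a count in a library. The mean log2 total was 20.96 ± 0.52 (SD, n = 49) in tumours and 20.81 ± 0.48 (SD, n = 10) in normals, a difference of 0.14 (permutation test, two-sided p = 0.43). The 10 most abundant genes took 10.8% ± 2.29 (SD) of counts in tumours and 12.5% ± 3.91 (SD) in normals (permutation p = 0.058, adjusted p = 0.29 over 5 library measures). Normal 7 had the highest share, at 21.1%.

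The first comparison asked which genes differed between tumours and normal cortex. Of 13004 genes tested, 66 were lower and 11 were higher in the libraries labelled tumour. The lower genes had a median log2 fold change of -0.97, with a range from -3.10 to -0.43, and 32 of them were lower by at least 2-fold. The higher genes changed less, with a median of 0.60 and a maximum of 0.99, and 0 of them reached 2-fold. In that direction the count at 2-fold was 5 with DESeq2, 0 with limma-voom, 7 with scaling by library totals alone, and 0 to 6 with each library left out in turn, the highest without normal 4. An unadjusted p under 0.05 was reached by 1661 genes (12.8%) in edgeR's quasi-likelihood test, where 650 would be expected by chance. How far this number varies between random splits of the libraries was not measured, so the excess was not tested. Of 100 splits of the 59 libraries into 49 and 10, the real one included, 16 gave as many called genes as the labels, and the highest other split gave 177 against the real 77.

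The called genes overlapped between tumours and normals. The median lower gene was below all 10 normals in 16 of 49 tumours (32.7%), where 9.09% would be expected of an unchanged gene. These genes were selected for a difference, so an excess over that value follows from the selection. For the median higher gene, 17 tumours (34.7%) exceeded all normals. The gene that parted the groups best among the lower genes did so in 38 tumours, and among the higher genes in 37. No called gene separated all tumours from all normals. The average log2 CPM was at or above the median of the genes tested for 44 of the 66 lower genes and 7 of the 11 higher genes, which a few high libraries can bring about, and 0 of the 77 reached the counting ceiling in any library.

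ENSCAFG00000003472 had the largest rise among called genes with an average log2 CPM at or above the median. Its level was 26.2 ± 10.2 CPM in tumours (SD, n = 49) and 13.2 ± 4.27 CPM in normals (SD, n = 10). The log2 fold change was 0.99 ± 0.20 (SE), with an adjusted p of 0.012 in edgeR's quasi-likelihood test. It exceeded all normals in 36 tumours. Its adjusted p ranged from 0.0027 to 1 over 73 alternative fits. The call was lost in 3, all of them fits of 20 libraries or against a fold of 1.5. It was kept without tumours 37 to 46, which held some of the highest levels, such as 50.7 CPM in tumour 40 and 48.8 CPM in tumour 38. Outside those 10 tumours, tumour 31 held 50.5 CPM. ENSCAFG00000036212 rose from 19.0 ± 3.74 CPM in normals to 30.3 ± 10.00 CPM in tumours, a log2 fold change of 0.67 ± 0.16 (SE; adjusted p = 0.031), and exceeded all normals in 37 tumours. Its call was lost when any one of 5 normals was left out, with edgeR adjusted p up to 0.086, although the log2 fold change stayed between 0.62 and 0.71 with each normal left out. In all, 11 of 73 alternative fits lost the call, and 0 of these 11 were among the 49 fits that left out 1 tumour. The adjusted p ranged from 0.019 to 1. Without tumours 37 to 46 its log2 fold change was 0.60 (edgeR adjusted p = 0.085).

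The fold changes and calls of the largest falls depended on single normals. ENSCAFG00000032615 was at 272 ± 601 CPM in tumours and 1957 ± 4785 CPM in normals, a log2 fold change of -2.85 ± 0.62 (SE; edgeR adjusted p = 0.019). It lay below all normals in 30 tumours, a count set by the lowest normal, normal 5 at 149 CPM. Among tumours 37 to 46 it ranged from 4.16 CPM in tumour 38, the lowest of all tumours, to 167 CPM in tumour 37. Normal 3 held 15512 CPM of it, and the other 9 normals held between 149 and 1673 CPM. Without normal 3 the log2 fold change was -0.73 and the edgeR adjusted p was 0.70. Over 73 alternative fits it ranged from 0.00075 to 0.70, and 8 of them lost the call. DESeq2 gave a log2 fold change of -1.04 and distinct UMIs gave -1.75, both without a call. ENSCAFG00000012011 was at 9.40 ± 23.0 CPM in tumours and 80.3 ± 161 CPM in normals, a log2 fold change of -3.10 ± 0.68 (SE; edgeR adjusted p = 0.019). Normal 10 held 500 CPM and normal 1 held 215 CPM, against 0.98 to 42.3 CPM in the other 8. Without normal 10 the log2 fold change was -1.86 and the edgeR adjusted p was 0.27, in a range from 0.0016 to 0.29 over 71 alternative fits, of which 5 lost the call. The call was also lost, at folds close to the main one, with DESeq2 (log2 fold change -3.09, adjusted p = 0.0514), with the depth covariate (-2.86, edgeR adjusted p = 0.0512) and without tumours 37 to 46 (-2.77, edgeR adjusted p = 0.0505). In 23 tumours it lay below all normals, a count set by the lowest normal, normal 5 at 0.98 CPM, and its counts reached down to 0.

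**Figure D1:**
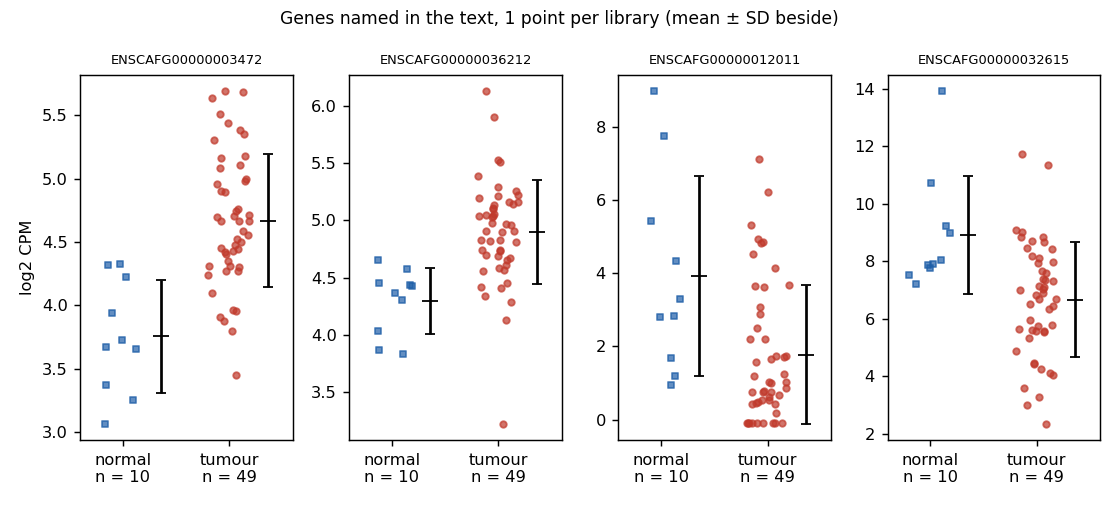
Expression of the 4 named genes (log2 CPM, y axis of each panel, which does not start at 0) in the 10 normals (squares) and 49 tumours (circles), 1 point per library, with the mean ± SD beside each group. The 2 genes on the left were higher in tumours with overlapping ranges, and in the right panel normal 3 lies at 13.9, far above the other normals.

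The counts of called genes depended on scaling and on single libraries. Scaling by library totals alone, without TMM, gave 71 higher and 17 lower genes and moved the median log2 fold change of all genes from 0.02 to 0.18. The number of lower genes was 137 without normal 2, 36 without normal 3, 28 without normal 5, 39 without normal 7 and 38 without normal 9. The number of higher genes was 30 without normal 4, 18 without normal 8, 19 without tumour 24, 7 without normal 6 or normal 10, 5 without normal 9, and 4 without normal 5 or normal 7. The number lower by at least 2-fold was 49 without normal 2 and 19 without normal 3 or normal 5. It was 15 with library totals alone, 21 with DESeq2, 13 with limma-voom, 13 with thinned libraries, 18 with the depth covariate and 60 with no filter on low counts.

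The second comparison asked how far the normal cortices stood apart from the tumours over all genes. The group label accounted for 2.81% of the squared distance between libraries, where random sets of 10 libraries gave 1.73% on average (permutation p = 0.088). Without normal 4 the share was 3.34% (permutation p = 0.049). The normals lay among the tumours on the first 2 principal components, which held 12.4% and 9.01% of the variance. The difference between group means was -5.77 on the first (permutation p = 0.55) and -8.50 on the second (permutation p = 0.29). The library most like a given normal was a tumour for 7 of the 10 normals and another normal for 3, where 15.5% of normals would match another normal by chance. This difference was not tested.

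**Figure D2:**
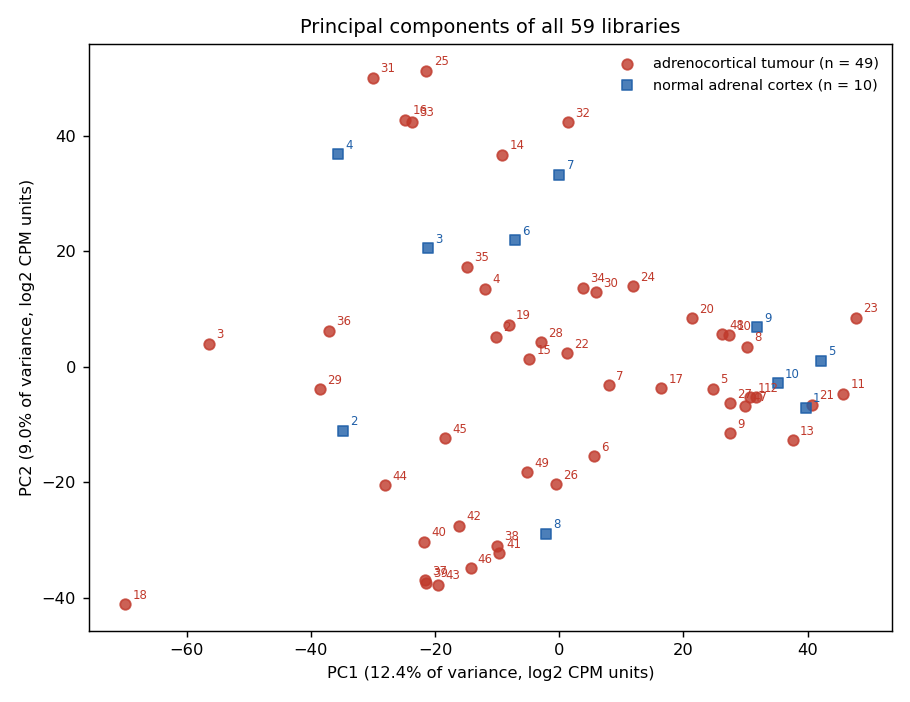
First principal component (x axis, 12.4% of variance) against the second (y axis, 9.0% of variance) of log2 CPM over 13004 genes, with 1 point per library, circles for tumours and squares for normals, and the number from each title. The 10 normals are spread over the range of the tumours, and tumours 37 to 43 and 46 lie close together at the lower left.

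The third comparison asked whether tumours were more varied than normals, since the title speaks of subtypes. No difference in spread was detected by either of 2 measures. The mean correlation among the 10 normals was 0.882, and random sets of 10 libraries gave 0.888, with a 95% range from 0.862 to 0.912 (permutation test, two-sided p = 0.57). Tumours had a mean correlation of 0.891. The median SD of a gene over libraries was 0.51 log2 CPM in tumours and 0.55 in normals. In 41.9% of genes the SD was larger in tumours, where random sets gave 56.2%, with a 95% range from 37.6% to 75.1% (permutation p = 0.15). Among normals, normal 4 correlated least with the others, at a mean of 0.841. Among tumours, tumour 18 correlated least with the other tumours, at a mean of 0.798.

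Tumours with neighbouring numbers resembled each other. The mean correlation between tumours next to each other in number was 0.903, against 0.891 in shuffled order (permutation p = 1e-05, the smallest that 100000 permutations can give). Without tumours 37 to 46 it was 0.890 against 0.886 (permutation p = 0.056). Tumours 37 to 46 had a mean correlation of 0.942 with each other, the highest of the 40 runs of 10 consecutive numbers. Libraries outside this run were about as close to it as some of its members. The mean correlation with the run was 0.941 for tumour 49, 0.939 for tumour 26 and 0.926 for normal 8, against 0.928 for its member tumour 44. Each run was compared with the other 49 libraries in the same edgeR test. The run 37 to 46 gave 898 genes at an adjusted p under 0.05, with 377 higher and 521 lower. A separate peak lay at tumours 27 to 36, which share no library with that run. They gave 516 genes, with 265 higher and 251 lower, at a mean correlation of 0.881 with each other. In 11 of the 40 runs the count exceeded the 77 genes of the normals, 5 of them around the first peak and 6 around the other, and the median run gave 34.5. The totals of tumours 37 to 46 lay between 1597111 and 2551958 counts. With these 10 tumours left out, the comparison of tumours with normals gave 8 higher and 54 lower genes. Of the 11 higher and 66 lower genes called with all libraries, 6 and 40 were called again.

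**Figure D3:**
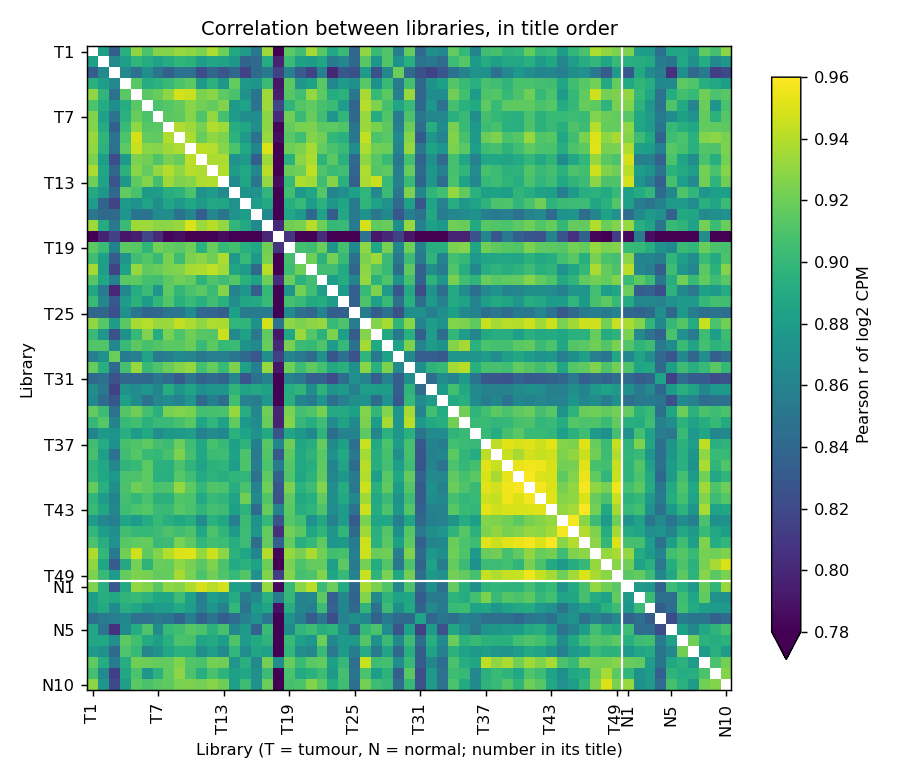
Pearson's r of log2 CPM between all 59 libraries, in the order of their titles (T for tumours, N for normals, with white lines between the groups; the diagonal is blank, and values under 0.78 have the darkest colour). Tumours 37 to 46 have a mean of 0.942 with each other and the normals 0.882, and tumours 26 and 49 have a mean of 0.939 and 0.941 with that run.

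**Figure D4:**
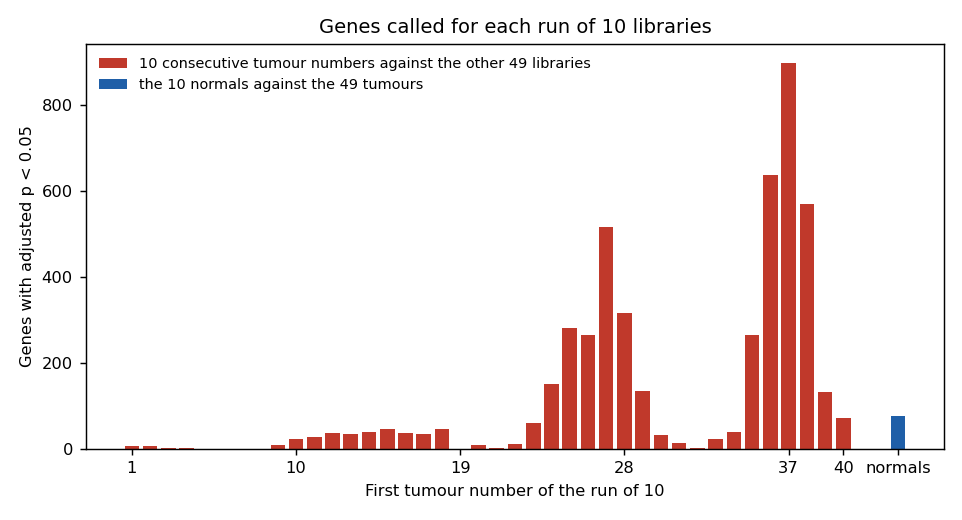
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test (y axis) for each run of 10 consecutive tumour numbers against the other 49 libraries (x axis, first number of the run) and for the 10 normals against the 49 tumours. The run 37 to 46 gave 898 genes, the run 27 to 36 gave 516 and the normals gave 77; neighbouring bars share up to 9 libraries.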

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

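The tests of both patterns in this part were chosen after the results were seen. Among 14 measures compared over the 10 normals, 3 had a library far from the others by Dixon's criterion, which chance exceeds in about 1 of 20 such sets. Normal 7 had 21.1% of its counts in the 10 most abundant genes. Normal 4 had a mean correlation of 0.841 with the other normals. Normal 3 had a log2 CPM of 13.9 for ENSCAFG00000032615. The 14 measures include the 4 named genes, which were chosen for large fold changes in these same libraries. The rate of 1 in 20 does not hold for them, so the flag of normal 3 is no independent result.

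The 77 genes called between tumours and normals are no more than random groupings of these libraries can give. Of 100 splits, 16 gave as many genes, and the highest other split gave 177, so chance cannot be excluded as the source of the count. The median of the other splits was 4 genes. The collision correction is not the source: with distinct UMIs 80 genes were called, within 1.5 times of the 77, although ENSCAFG00000032615 was not among them. A real difference between tumour and normal cortex in part of the genes stays open.

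Tumours 37 to 46 gave 898 genes, against 177 for the highest random split and 77 for the normals. They were singled out as the highest of the 40 runs, so this contrast is no independent test. They are not the only run above these counts, since tumours 27 to 36 gave 516. Tumours 27 to 36 were less alike, with a mean correlation of 0.881 against 0.942. They were compared with libraries that include tumours 37 to 46, and no fit of them without those was made. Depth does not account for the genes of the run 37 to 46: 912 were called with log2 library total as a covariate. With the 54 deepest libraries thinned to the same total 538 were called, a fit that also lost reads and 5 libraries. Both other technical explanations that were examined stay open, and further ones, such as RNA quality, were not examined. Libraries made or sequenced together could give totals as alike as these: the SD of their log2 totals was 0.19, the lowest of the 40 runs, against 0.52 over all tumours (permutation p = 0.00123, not corrected for the choice of run). An exchange of labels between the groups was not excluded either. The 10 libraries labelled normal were no more alike than random sets of 10 (permutation p = 0.57), which does not show that labels were exchanged. That comparison did not look at tumours 37 to 46 as a set and would come out the same for varied normals, so it cannot decide. A class of similar tumours that were numbered together was not tested, since the labels name no class.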

How the results depend on the processing

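The counts of 11 higher and 66 lower genes moved with many settings. Higher and lower genes numbered 71 and 17 with library totals only, 30 and 97 with DESeq2, 5 and 25 with limma-voom, 7 and 36 with the depth covariate, and 1 and 13 with thinned libraries. There were 7 higher genes with no filter, and against a fold of 1.5 there were 0 higher genes and 1 lower. Leaving out each library in turn gave 4 to 30 higher and 28 to 137 lower genes. Median ratio scaling, the stricter filter, distinct UMIs, leaving out genes that reached the ceiling, and leaving out tumours 37 to 46 kept both counts within 1.5 times; the last 3 were chosen after seeing the data, as were the tumours left out in turn. The cause of these moves was not tested. Similar counts did not always hold the same genes. Of the main 11 higher and 66 lower genes, 11 and 66 were called again with median ratio scaling and 11 and 61 with distinct UMIs. Without tumours 37 to 46 it was 6 and 40, with DESeq2 10 and 47, and with limma-voom 4 and 15. The directions of all 77 genes held with median ratio scaling and with library totals, against 72 with DESeq2 and 76 with limma-voom. Counting genes not tested as not held, it was 73 without normal 3 and 66 in the fits of 20 libraries. For the 4 named genes no fit reversed the direction, and 27 of 290 fits lost the call. For each gene 49 of the fits left out 1 tumour, and 0 of those lost the call. All 27 losses therefore fell among the remaining fits. The share along the group label ranged from 2.29% to 3.34% with each normal left out, and passed the threshold only without normal 4 (3.34%, permutation p = 0.049); the correlation among normals, the SD comparison and library totals kept their side of the threshold in the alternatives run. Whether the numbers in the titles pair the samples was not settled. Same-numbered tumours and normals correlated in their deviations at over 0.1 in 5 of 10 pairs, from -0.09 to 0.27. No such range was taken from pairs of different numbers. When each library was matched over all 10 numbers, 2 normals and 1 tumour correlated best with their own number, and most did not. With the replicate block over these 20 libraries 0 genes were higher and 1 was lower; without it the counts were 1 and 6. Alternatives for gene lists, list scores and relations were not run, for want of gene symbols, and no library was shallow enough to be left out for its total. With thinning, which also left out 5 libraries, 11105 genes were tested, and the ceiling of 34070 limits 21 abundant genes.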

Other observations

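The tests in this part were chosen after the results were seen. Single tumours had genes far outside the range of the normals. Of 13004 genes, 304 lay over 4-fold above all 10 normals in at least 1 tumour, and 302 of these did so in no more than 4 tumours. Over 4-fold below all normals were 210 genes, of which 12 did so in 5 or more tumours and 1 gene at most in 11. The median tumour had 3 such genes above and 5 below. Tumour 18 had the most, with 111 above and 34 below. Compared with the other 9 normals, a normal had a median of 6.5 genes above, up to 39 in normal 3, and a tumour compared with 9 normals had a median of 3. Below the other normals the medians were 4 for a normal, up to 40 in normal 7, and 6 for a tumour.

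Genes with neighbouring identifiers moved together in most libraries. Over 6638 genes ordered by identifier, the SD of a running mean over 100 genes was compared with that in shuffled orders, and it was larger in 46 of 49 tumours and 10 of 10 normals (adjusted p under 0.05). One hypothesis was that these runs come from copy number changes in the tumours alone, if identifiers follow the order of genes on chromosomes, which was not checked here. The ratio to shuffled order was 1.47 ± 0.27 (SD, n = 49) in tumours and 1.47 ± 0.26 (SD, n = 10) in normals. The difference was 0.0043 with a standard error of 0.092 (permutation p = 0.96), so the tumour mean did not exceed the normal mean as predicted. However, each gene had been centred on its median over all libraries, most of them tumours. A change shared by most tumours would be removed from them and appear in the normals. Equal means therefore cannot decide the hypothesis. The highest ratios were 2.44 in tumour 16, 2.17 in tumour 34 and 1.98 in normal 7.

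Whether the 49 tumours fall into 2 classes over all genes was tested with the 2-means index on 10 principal components. The index was 0.825, against 0.816 ± 0.023 (SD) in 1000 simulations of a single class (p = 0.630). The test has little to say, because it recovered 0% of 50 simulated sets with 2 classes set 2 SD apart on the leading component.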
